A study of Mus musculus with 24 samples.

How the data were processed

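The data are small RNA sequencing libraries from 3T9 cells, an immortalised line of mouse embryo fibroblasts. Newly made RNA was marked with 4-thiouridine (4SU), a uridine analogue that cells build into RNA and whose thiol group can be coupled to biotin. Per the labels, cells received 300 µM 4SU for 3 h (the pulse) and were then moved to 1 mM uridine (the chase), and labelled RNA was biotinylated, captured on streptavidin beads and used for Illumina TruSeq small RNA libraries. The labelled series holds 21 libraries: 7 time points (0, 2, 4, 6, 8, 10 and 12 h of chase) in each of 3 experiments, which the series design calls independent replicates. Another 3 libraries served as controls, 1 of each kind. They were total RNA of unlabelled cells, total RNA of 4SU-pulsed cells, and an extraction carried out on unlabelled cells, called the negative extraction here.

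The table the authors deposited holds read counts, whole numbers whose library totals differ, with one column per library, for 20 isoform classes of each mature miRNA. The table had 7129 entries for 1221 mature miRNA names, and 1 entry that occurred in duplicate was removed. The classes separate the canonical sequence, trimmed forms, templated extensions at either end and non-templated additions. Entries for all non-templated additions at an end were compared with the sum of the entries by added base. Repeated entries for non-templated canonical and trimmed forms were compared with each other as well. Values were equal in 25728 of 25728 cells tested over both checks, so each such total or repeat was used once. Summing every entry would have raised the library totals by a factor of 1.12 to 1.18. Base calling was done with CASAVA 1.8.0, per the submitters' processing notes. The aligner, the miRNA annotation, the rule for reads that match several miRNAs and the definitions of the isoform classes are not given in the sources used here. Reads of near-identical miRNAs, such as the miR-466, miR-467 and miR-669 paralogs, may have been divided among names or counted several times, so single members of these families are uncertain.

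The second header line of the table holds a code that the labels do not explain; it was read as a sequencing run and is called the run code. Experiment 1 and the negative extraction share one code, experiments 2 and 3 have a code each, and both total RNA libraries share a further one. The experiment and this code therefore coincide, and labelled and total RNA libraries never share a code.

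Counts were summed per mature miRNA. Depth, taken as the summed miRNA count, was 1133048 to 7886484 in the labelled libraries, 6412428 in total unlabelled RNA, 4525638 in total 4SU RNA and 283922 in the negative extraction. A level of 3 counts corresponded to 0.38 to 2.65 CPM (counts scaled to one common library total) in the labelled libraries and to 10.6 CPM in the negative extraction. The 10 most abundant miRNAs took 59.7 to 70.8% of the counts. Intervals and count floors cover counting error only, because the reads carry no molecular identifiers.

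The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM normalisation, which assumes that most miRNAs keep their proportions, and filterByExpr with the time points as groups. It was run on 414 miRNAs, with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values of single miRNAs are from this test throughout. It gave 4 results: the slope in log2 per hour of chase, the contrasts of 12 h and of 2 h against 0 h, and a change of slope at 4 h. No spike-in or absolute amount enters, so a slope is relative: above 0 a miRNA gained share in the purified pool, and below 0 it lost share. It is not a half-life. The main model had no term for the experiment. The experiment number pairs the libraries: deviations from the time-point means correlated at 0.311 to 0.738 (median 0.557) in all 63 pairs of libraries from one experiment, against -0.647 to 0.227 (median -0.338) in the 126 pairs from different experiments, and 21 of 21 libraries correlated best with a library of their own experiment. Fits with the experiment as a block were therefore run too, and their counts, such as 132 miRNAs for the slope, stand beside each result that they changed.

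Arms were compared in 95 hairpins with both arms tested. The major arm is the one with more counts in the 2 total RNA libraries. The measure was the median over hairpins of log2 of minor over major arm, with a pseudocount of 1 CPM. This measure and the isoform shares were tested by permuting time points within experiments, two-sided, with 100000 resamples, for which 1e-05 is the smallest p that can be obtained. The 11 isoform classes tested formed one family for adjustment. Gene lists were tested with camera (limma 3.58.1) on log-CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 15 lists with at least 3 tested members. Single control libraries were compared without a test, as log2 ratios of CPM with a pseudocount of 1. List medians of these ratios were placed among 10000 random lists matched on mean expression. Coordinates are 1-based positions of miRNA genes in GENCODE vM21 (GRCm38), matched by name. There, 1126 mature names matched 1 gene, 52 matched several and 43 matched none, and no coordinate is printed for the latter. A miRNA gene is called exonic if it overlaps an exon of any annotated transcript of its host gene on the same strand. It is called intronic otherwise, and an exonic one can be intronic in other transcripts.

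The design, the lists, the rule for named miRNAs and the other settings, except those named below, were fixed before the data were examined. List members were chosen by name and not by position in the genome. The 19 lists were the let-7, extended miR-16, miR-30, miR-29, miR-34 and miR-181 families, the miR-17~92 and miR-106b~25, miR-221/222, miR-23/27/24, Sfmbt2 intronic and Dlk1-Dio3 clusters, the miR-10/99/100/125 group, mesenchymal miRNAs, miRNAs for which target-directed degradation has been reported, and blood cell, epithelial, neural, muscle and embryonic stem cell miRNAs; 235 of 239 member names were in the table. Named miRNAs were, among those with a mean of at least 10 CPM over the labelled libraries, the 10 highest and 10 lowest slopes past the threshold with the same sign in every experiment, the 5 highest and 5 lowest changes past the threshold at 2 h, and further the 5 most abundant in unlabelled total RNA, the 2 most abundant members of each list, the 3 hairpins at either end of the arm difference, and the 5 highest and 5 lowest ratios of labelled to total RNA with at least 50 counts in each library. The minimum of 10 CPM in the rule was not applied to list members and hairpin arms, some of which lie below it. Other miRNAs are named only with the statement that they were chosen after their values were seen, or as members of a list.

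Alternatives were other normalisations, filters, DESeq2 1.42.0, limma-voom, the block, leaving out experiments, libraries or time points, other pseudocounts, and other list tests. Chosen after seeing the data were thinning every library to 1133048 counts, combinations of the block with another choice, isoform shares at a fixed mix of miRNAs and with experiments or the 0 h point left out, and for the arms a minimum of 100 CPM and leaving out 0 h. The tests were tried on simulated counts with known slopes over 414 miRNAs. Without the block, 97% of slopes of 0.15 log2 per hour and 22% of slopes of 0.05 were recovered, with 0 of 214 unchanged miRNAs called. With the block, 99% and 60% were recovered, with 5 of 214 unchanged miRNAs called. In simulated lists, camera called 2 of 2 changed and 0 of 20 unchanged ones. Counts were simulated independently for each miRNA, so this does not show how often camera errs in lists whose members vary together. A planned comparison with the uridine content of each miRNA was not run, because mature sequences are not used here. Figures were drawn with matplotlib 3.10.9 from values computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.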

Results

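Mature miRNAs were counted in 24 small RNA libraries of mouse 3T9 fibroblasts. In 21 libraries the RNA had been purified through its 4SU label, at 0, 2, 4, 6, 8, 10 and 12 h of chase with 3 experiments at each time. The other 3 libraries, with 1 of each kind and so no replicates, were total RNA of unlabelled cells, total RNA of 4SU-pulsed cells and the negative extraction from unlabelled cells. Depth fell over the chase, from 7733333 to 3281631 counts in experiment 1, from 3019171 to 1133048 in experiment 2 and from 4613499 to 2533106 in experiment 3. At 12 h a level of 3 counts corresponded to 0.914, 2.65 and 1.18 CPM in the 3 experiments. Values at single time points are means ± SD with n = 3. CPM values are scaled by library totals without TMM. They can therefore differ in size or direction from the slopes and folds, which use it.

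The slope over all 21 purified libraries asked which miRNAs gained or lost share among labelled miRNAs as the chase went on, the study's route to miRNA decay. Among the miRNAs that rose, miR-301a-3p had the highest slope, 0.21 log2 per hour (SE 0.04, adjusted p = 0.00163), and went from 64.0 ± 35.6 to 213 ± 62.0 CPM between 0 and 12 h. miR-3061-3p rose by 0.12 per hour (SE 0.016, adjusted p = 3.32e-05), from 34.3 ± 3.76 to 76.6 ± 3.62 CPM. Its gene overlaps an annotated exon of Ppp2ca (chromosome 11, 52126746 to 52126836). miR-19b-3p and miR-92a-3p, products of the growth-promoting miR-17~92 cluster, rose by 0.12 (SE 0.0255, adjusted p = 0.00275) and 0.07 per hour (SE 0.0178, adjusted p = 0.00897). The latter went from 79886 ± 17924 to 127200 ± 27695 CPM. miR-21a-5p, abundant in fibroblasts, rose by 0.06 per hour (SE 0.0153, adjusted p = 0.00897), from 55464 ± 12048 to 77390 ± 21114 CPM. Its gene overlaps an annotated exon of Vmp1 (chromosome 11, 86584067 to 86584158). miR-186-5p (Zranb2 intron, chromosome 3, 157544279 to 157544349) and miR-148b-3p (Copz1 intron, chromosome 15, 103285125 to 103285221) rose by 0.07 and 0.06 per hour, with adjusted p of 0.00152 and 0.00026. The rises of miR-130a-3p (chromosome 2, 84741115 to 84741178), miR-450b-5p (chromosome X, 53047997 to 53048078) and miR-7224-3p (B3galt1 intron, chromosome 2, 67675457 to 67675516) were 0.05, 0.08 and 0.05 per hour, with adjusted p of 0.00152, 0.0311 and 0.0311.

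Among the miRNAs that fell, miR-669a-3p had the lowest slope, -0.22 log2 per hour (SE 0.0606, adjusted p = 0.0183), and went from 114 ± 84.5 to 18.5 ± 11.1 CPM. Its name matches 12 gene copies. miR-92a-1-5p, the opposite strand of the hairpin that gives miR-92a-3p, had a slope of -0.18 (SE 0.034, adjusted p = 0.00163) and went from 651 ± 161 to 105 ± 56.3 CPM. miR-29b-1-5p (chromosome 6, 31063023 to 31063093), likewise the passenger of a better-known arm, had a slope of -0.18 (SE 0.0346, adjusted p = 0.00163) and went from 68.6 ± 41.9 to 16.5 ± 7.34 CPM. miR-335-5p, from an intron of the imprinted gene Mest (chromosome 6, 30741299 to 30741396), had a slope of -0.15 (SE 0.0379, adjusted p = 0.00897) and went from 497 ± 340 to 113 ± 40.0 CPM. miR-214-3p had a slope of -0.11 (SE 0.0345, adjusted p = 0.0311) and went from 2214 ± 1265 to 733 ± 407 CPM. Its gene overlaps an annotated exon of Dnm3os, a noncoding RNA antisense to Dnm3 (chromosome 1, 162223368 to 162223477). miR-671-5p (annotated Chpf2 exon, chromosome 5, 24592114 to 24592211) and miR-8112 (chromosome 6, 71271671 to 71271801) had slopes of -0.14 and -0.09, with adjusted p of 0.013 and 0.0476. Of the Sfmbt2 list, miR-466h-3p (chromosome 2, 10514891 to 10514971), miR-466d-3p (chromosome 2, 10511967 to 10512062) and miR-466b-3p (8 gene copies) had slopes of -0.17, -0.16 and -0.10, with adjusted p of 0.0283, 0.00391 and 0.0283.

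**Figure D1:**
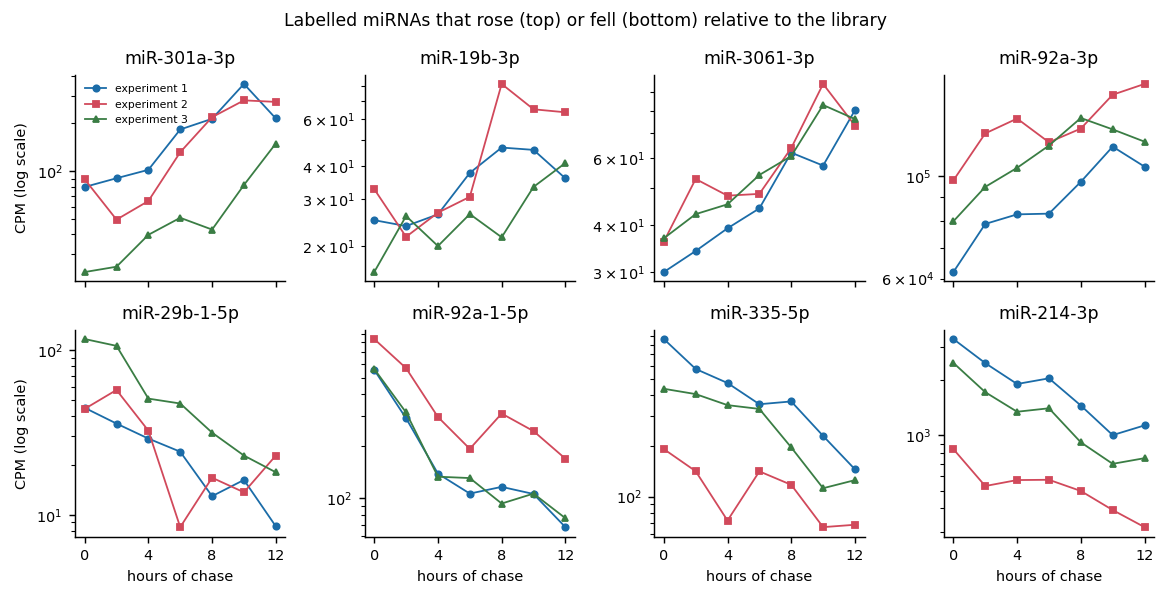
Level in CPM (log scale) against hours of chase for 8 miRNAs, with a line for each of the 3 experiments. In the top panels are miR-301a-3p, miR-19b-3p, miR-3061-3p and miR-92a-3p, which rose, and in the bottom panels miR-29b-1-5p, miR-92a-1-5p, miR-335-5p and miR-214-3p, which fell.

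In all, 51 of 414 miRNAs passed the threshold for the slope, 21 up and 30 down. With the experiment as a block the count was 132, 63 up and 69 down, and included each of the 51. Slopes are relative to the other miRNAs, and the scaling sets the split: 10 of 57 calls were up (17.5%) when only total counts were used, which put the median slope of all miRNAs at -0.0231 rather than -0.0037. It was 39 of 63 up (61.9%) with upper-quartile scaling. In fits without the block the count was 29 without the 0 h library of experiment 1, 17 without 0 h and 22 without 12 h. It was 20, 77 and 15 without experiment 1, 2 or 3. With the block and without 0 h, a setting chosen after seeing the data, 97 miRNAs were called, among them 41 of the 51. The lost calls given next are all from fits without the block. Without 0 h the calls of miR-21a-5p and miR-92a-3p (adjusted p = 0.0827 and 0.179) and of 9 of the 10 named fallers, all but miR-29b-1-5p, were lost, as were those of miR-450b-5p and miR-7224-3p, which scaling by total counts also ended (0.123 and 0.206). Most named fallers also lost their calls without 12 h, with adjusted p of 0.0531 (miR-671-5p) to 0.175 (miR-8112), and without experiment 1 or 3. The call of miR-92a-3p was lost without experiment 3 (adjusted p = 0.137) and that of miR-21a-5p without experiment 2 (0.142). miR-335-5p was not past the threshold without the 0 h library of experiment 1 (adjusted p = 0.0545), nor miR-669a-3p without that of experiment 3 (0.0591). limma-voom ended the calls of miR-669a-3p (adjusted p = 0.105), miR-466h-3p (0.0588) and miR-214-3p (0.0577), upper-quartile scaling that of miR-8112 (0.0738), and no filter on low counts those of miR-7224-3p, miR-450b-5p and miR-8112 (0.214, 0.126 and 0.108). Leaving out any one of several libraries ended the calls of miR-214-3p, miR-466b-3p, miR-466h-3p, miR-450b-5p, miR-7224-3p and miR-8112, with adjusted p of up to 0.118, 0.125, 0.0769, 0.0771, 0.0769 and 0.0943.

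The miR-17~92 and miR-106b~25 clusters, whose miRNAs promote proliferation, held 16 tested miRNAs, of which 4 rose and 1 fell. The counts were 6 and 1 adjusted over the list alone, and 8 and 1 with the block. The risers were miR-92a-3p, miR-19b-3p, miR-25-3p (0.04 per hour, adjusted p = 0.0131, from 9100 ± 473 to 11160 ± 1322 CPM) and the scarce miR-19a-3p (0.16 per hour, adjusted p = 0.0337). The faller was miR-92a-1-5p. The gene of miR-25-3p overlaps an annotated exon of Mcm7 (chromosome 5, 138165321 to 138165404). In edgeR miR-25-3p had an adjusted p of 0.16 with total counts only. Slopes were positive for 14 members, or for 9 when only total counts were used, and camera placed the list above other miRNAs (adjusted p = 0.00405). That call was lost with an estimated correlation (adjusted p = 0.133) and without experiment 2 (0.143). The miR-29 family, known to repress collagen mRNAs, had 3 tested members with positive slopes under every scaling. camera placed it above other miRNAs too (adjusted p = 0.0136), with adjusted p = 0.458 with an estimated correlation and 0.143 without experiment 2. Of its members 1 passed over all genes, miR-29c-3p (0.11 per hour, adjusted p = 0.0211), against 3 adjusted over the list alone and 3 with the block. The slope of miR-29a-3p was 0.04 (adjusted p = 0.0594) and that of miR-29b-3p 0.08 (adjusted p = 0.0759).

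The list for the Sfmbt2 intronic cluster, a rodent-specific array of repeated miRNA genes, had 30 tested members. It holds every name with the stem miR-297, miR-466, miR-467 or miR-669, whether or not its gene lies in Sfmbt2. Of the 30, 6 fell and 0 rose in edgeR, against 8 and 0 adjusted over the list alone and 14 and 0 with the block. Slopes were negative for 27 members, and for 27 to 29 under the other scalings. camera placed the list below other miRNAs (adjusted p = 9.44e-05). That call was lost with an estimated correlation (adjusted p = 0.744), also when the block was added to it (0.11). With fry, which tests a list against no change, the adjusted p was 0.186, or 2.15e-05 with the block. Besides those named above, miR-466g and miR-669f-3p fell (slopes -0.12 and -0.16, adjusted p = 0.036 and 0.045), and stood at 4.14 and 1.61 CPM at 12 h. The 2 most abundant members, miR-669a-5p and miR-669c-5p, had slopes of 0.00 and -0.05 and did not pass (adjusted p = 0.984 and 0.0907), though the latter was called with the block (adjusted p = 0.000319).

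Of the 11 tested miRNAs of the miR-23/27/24 clusters, 0 rose and 3 fell by edgeR, against 1 and 5 adjusted over the list alone and 2 and 5 with the block. For this list camera gave adjusted p = 0.16. The fallers were 5p arms: miR-27a-5p (slope -0.08, adjusted p = 0.0103, from 217 ± 45.6 to 79.9 ± 11.9 CPM), miR-23b-5p (slope -0.12, adjusted p = 0.0211) and miR-27b-5p (slope -0.03, adjusted p = 0.036, from 834 ± 23.6 to 528 ± 19.1 CPM). Their abundant 3p partners had slopes of 0.04 (miR-27b-3p, adjusted p = 0.11, or 0.000919 with the block) and -0.01 (miR-23b-3p, adjusted p = 0.653). In the cluster of miR-221 and miR-222, which targets a cell cycle inhibitor, 1 of 4 tested miRNAs fell over all genes, adjusted over the list alone and with the block. It was miR-221-5p (slope -0.08, adjusted p = 0.0232, from 721 ± 275 to 280 ± 92.2 CPM). miR-222-3p and miR-221-3p had slopes of -0.01 and 0.01 (adjusted p = 0.837 and 0.734). Mesenchymal miRNAs had 10 tested members, of which 1 rose (miR-21a-5p) and 1 fell (miR-214-3p), or 2 and 1 adjusted over the list alone, and 2 and 2 with the block. The slope of miR-143-3p, one of the most abundant miRNAs here, was 0.00 (SE 0.0212, adjusted p = 0.996). In the group of miR-10, miR-99, miR-100 and miR-125, with 7 tested, 1 rose (miR-125b-5p, 0.03 per hour, adjusted p = 0.0363, from 10563 ± 919 to 11839 ± 1219 CPM) and 1 fell (miR-100-5p, slope -0.06, adjusted p = 0.00813, from 3544 ± 519 to 1872 ± 434 CPM), against 2 and 1 adjusted over the list alone and with the block. Its most abundant members, miR-99b-5p and miR-125a-5p, had slopes of -0.02 and 0.00 (adjusted p = 0.381 and 1.0).

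In the let-7 family, an antagonist of growth programmes, 0 of 9 members passed in edgeR over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05 and 0 in DESeq2 or limma-voom, and with the block 1 had a positive slope (let-7i-5p) and 1 a negative slope (let-7b-5p) past the threshold. Signs in this family depend on the scaling: 4 of 9 slopes were positive with the main scaling, 1 with total counts only and 7 with upper-quartile scaling, and let-7i-5p was not called with the block and total counts only (adjusted p = 0.451). let-7f-5p went from 118740 ± 21470 to 107570 ± 28158 CPM and let-7i-5p from 54475 ± 6299 to 54301 ± 1980 CPM. With the main scaling their slopes were above 0 all the same (0.01 and 0.03, adjusted p = 0.816 and 0.0646). The miR-181 family had 4 positive slopes under every scaling and 0 calls of 4 over all genes or adjusted over the list alone, but 4 calls with the block. miR-181a-5p and miR-181b-5p had slopes of 0.03 and 0.04 (adjusted p = 0.284 and 0.283). At an unadjusted p under 0.05 there was 1, and DESeq2 and limma-voom called 0. camera gave adjusted p = 0.0663 for that family, 0.0178 with the block, and adjusted p = 0.236 with the block and an estimated correlation. The edgeR count was also 0, over all genes and adjusted over the list alone, in the extended miR-16 family (7 tested), the miR-30 family (5), the miR-34 family (4), the Dlk1-Dio3 cluster (4), the miRNAs with reported target-directed degradation (7) and neural miRNAs (4). The camera adjusted p was 0.992 for each except the miR-30 family (0.648). At an unadjusted p under 0.05 these 6 lists held 2, 1, 1, 0, 2 and 0 miRNAs, DESeq2 called 1, 0, 0, 0, 2 and 0, and limma-voom called 1, 0, 0, 0, 1 and 0. With the block, calls up and down were 2 and 1 in the miR-16 family, 2 and 0 in the miR-30 family, 0 and 1 in the miR-34 family and 1 and 2 among the target-directed group. miR-16-5p, a brake on the cell cycle, had a slope of 0.05 (adjusted p = 0.181, or 3.84e-05 with the block), miR-30d-5p 0.00 (adjusted p = 0.852) and miR-30a-5p 0.03 (0.553, or 0.04998 with the block). The slope of miR-34c-5p was 0.03 (adjusted p = 0.267), miR-34a-5p 0.02 (0.745), miR-322-5p 0.01 (0.852) and miR-30c-5p 0.01 (0.795). The signs of the list medians for the let-7, miR-16, miR-30 and miR-34 families, the cluster of miR-221 and miR-222, the group of miR-10, miR-99, miR-100 and miR-125, the target-directed group and neural miRNAs flipped under at least one scaling. Median and mean slope differed in sign in the miR-16 and miR-34 families, and the median and camera's direction in the let-7, mesenchymal and neural lists.

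Markers of other cell types were scarce or had no called slope. Of blood cell miRNAs, miR-486a-5p averaged 428 CPM and miR-150-5p 3.74 CPM over the labelled libraries (slopes 0.02 and 0.05, adjusted p = 0.775 and 0.384). Of epithelial miRNAs, miR-205-5p averaged 534 CPM and miR-203-3p 3.24 CPM (slopes -0.05 and -0.02, adjusted p = 0.348 and 0.866). miR-205-5p was called with the block (adjusted p = 0.000319). The muscle miRNA miR-206-3p averaged 9.02 CPM (slope -0.06, adjusted p = 0.368, or 0.0222 with the block). In edgeR 0 members of these 3 lists passed over all genes, adjusted over the list alone or at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. miR-128-3p and miR-129-5p of the neural list had slopes of 0.01 and 0.00 (adjusted p = 0.695 and 0.956), and miR-376a-5p and miR-541-5p of the Dlk1-Dio3 cluster stood at 7.29 and 5.67 CPM with slopes of -0.05 and 0.05 (adjusted p = 0.852 and 0.489). Of the embryonic stem cell list 0 of 6 members were abundant enough to test.

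**Figure D2:**
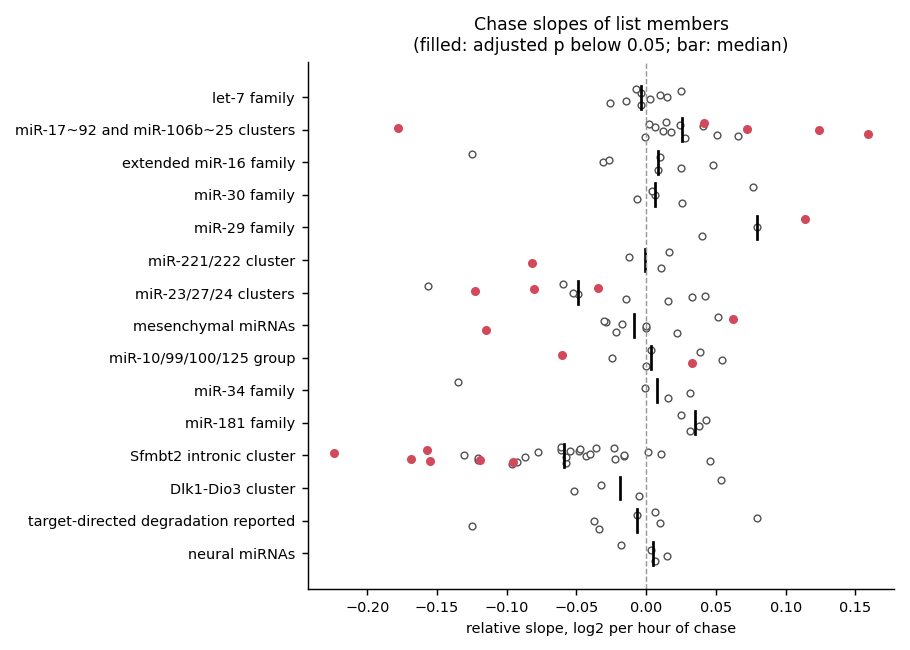
Slope in log2 per hour of chase for each tested member of the 15 lists with at least 3 tested members; filled points passed an adjusted p of 0.05 and each bar marks the list median. Of the 30 Sfmbt2 members 27 lie below 0, and the 3 miR-29 members lie above it.

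The contrast of 12 h with 0 h asked how far the pool had moved by the end of the chase. miR-3061-3p rose 2.64-fold (adjusted p = 0.0164) and miR-148b-3p 1.65-fold (adjusted p = 0.0442). miR-92a-1-5p fell to 0.191 of its 0 h level (adjusted p = 0.0442). Also past the threshold were miR-16-1-3p, a passenger strand that went from 16.6 ± 7.61 to 2.64 ± 1.55 CPM (adjusted p = 0.0442), and miR-503-5p, for which target-directed degradation has been reported, from 4.27 ± 0.142 to 0.335 ± 0.309 CPM (adjusted p = 0.0442). The latter is below the level of 3 counts in each experiment, so no fold is given, and both were chosen after their values were seen. These 5 miRNAs, 2 up and 3 down, were all that passed in edgeR of 53 with an unadjusted p under 0.05. With the block 90 passed, 40 up and 50 down. DESeq2 gave 15, scaling by total counts 14 (1 up and 13 down, with the median of all miRNAs at -0.29 rather than -0.05 log2), upper-quartile scaling 8 (5 up) and no filter 10. The count was 0 with libraries thinned to equal depth, with the 6 compared libraries alone, or without the 0 h or 12 h library of experiment 1, the 0 h library of experiment 2 or the 12 h library of experiment 3, and it was 2 without the 0 h library of experiment 3.

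The contrast of 2 h with 0 h asked what moved in the first step of the chase. The miRNAs named for it were called with the block and chosen after their values were seen. miR-30d-3p went from 140 ± 58.7 to 57.7 ± 16.3 CPM (-1.22 log2, adjusted p = 0.00496) and miR-125b-1-3p from 8311 ± 2014 to 5418 ± 1155 CPM (-0.56, adjusted p = 0.0104), while miR-149-5p rose from 480 ± 141 to 676 ± 144 CPM (0.58, adjusted p = 0.0111). Without the block edgeR called 0 miRNAs, with 10 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 1 each. With the block 14 were called, 13 down and 1 up. Of these 5 were minor and 2 major arms of the hairpins compared below.

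The slope after 4 h was compared with the slope before it to see whether change was even over the chase. With the block, 18 miRNAs differed: for 14 the slope was higher after 4 h than before, and for 4 it was lower. Of the 18, 10 were also called at 2 h with the block, and both tests use the same 0 h libraries. The slope of miR-92a-1-5p changed by 0.38 log2 per hour (adjusted p = 1.4e-05), and its level went from 651 ± 161 CPM at 0 h to 189 ± 92.2 at 4 h and 105 ± 56.3 at 12 h. miR-30d-3p (change of 0.50) went from 140 ± 58.7 to 43.0 ± 18.5 and then to 69.9 ± 46.4 CPM. miR-149-5p had a change of -0.23, the most negative of the 4. These were chosen after their values were seen. Without the block edgeR called 0, with 20 at an unadjusted p under 0.05, DESeq2 called 5 and limma-voom 0, and edgeR called 3 without experiment 2.

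Each miRNA hairpin yields a 5p and a 3p arm, and the arms were compared to ask whether the scarcer (minor) arm lost share in the labelled pool faster than its partner. Across 95 hairpins the median log2 ratio of minor to major arm fell from -2.52 ± 0.06 at 0 h to -2.96 ± 0.27 at 12 h, with a slope of -0.03 per hour (SD 0.0172, n = 3 experiments, permutation p = 0.00089). The ratio was lower with time in 3 of 3 experiments. In the control libraries it was -2.94 in unlabelled total RNA, -2.82 in total 4SU RNA and -3.01 in the negative extraction. The mean at 12 h lies within this range, with -2.85, -3.26 and -2.76 in experiments 1, 2 and 3. Unlabelled RNA carried through the purification could thus give a fall of the mean, and was not separated from faster loss of minor arms. The minor arm had the lower slope in 67 of 95 hairpins, and in all 3 experiments for 34, against 7 with the higher slope in all 3, where chance gives 11.9 each way. Of the minor arms 15 fell and 0 rose over the chase in edgeR, or 23 and 7 with the block, and of the major arms 3 fell and 8 rose, or 10 and 21 with the block.

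The largest differences toward loss of the minor arm were in Mir450b (-0.18 ± 0.0165 log2 per hour, SD, n = 3), Mir34c (-0.15 ± 0.0797) and Mir467d (-0.15 ± 0.0488), though the minor arms miR-34c-3p and miR-450b-3p averaged only 1.76 and 3.85 CPM. Hairpins at the other end were Mir214 (0.11 ± 0.0156), in which the minor arm miR-214-5p had a slope of 0.00 and the major arm miR-214-3p fell, Mir98 (0.07 ± 0.0278) and Mir542 (0.07 ± 0.0938, less than its spread). With both arms required to average at least 10 CPM, 61 hairpins were left and the slope of -0.02 no longer passed (-0.0225, permutation p = 0.0501), while with minor arms of at least 100 CPM, a limit chosen after seeing the data, 25 hairpins gave -0.03 (permutation p = 0.00653). The slope was -0.0501 with a pseudocount of 0.1 CPM and -0.0185 without experiment 2, against -0.0282.

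**Figure D3:**
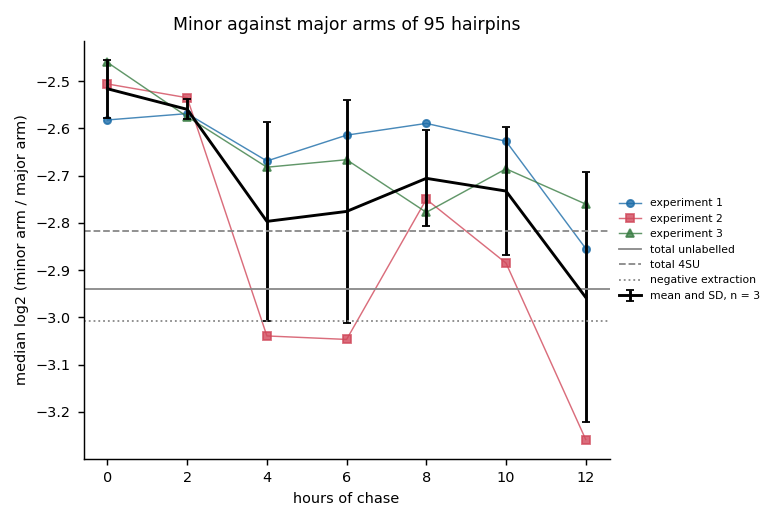
Median over 95 hairpins of log2 minor over major arm against hours of chase, as points for each experiment and mean ± SD (n = 3), with horizontal lines for the 3 control libraries. The mean goes from -2.52 at 0 h to -2.96 at 12 h.

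Isoform classes were followed to ask whether the ends of labelled miRNAs changed with age. Reads with bases added at the 3′ end that do not match the genome rose from 12.9 ± 0.81% of miRNA counts at 0 h to 16.1 ± 1.82% at 12 h, by 0.268 percentage points per hour (SD 0.102, n = 3, permutation p = 1e-05, adjusted p = 2.2e-05, higher with time in 3 of 3 experiments). Additions of mixed bases rose from 4.96 ± 0.772 to 8.02 ± 1.23% (0.254 points per hour, adjusted permutation p = 2.2e-05), and C additions rose too, from 0.716 ± 0.257 to 1.16 ± 0.432% (0.0363 points per hour, adjusted permutation p = 0.000587, or 0.101 without experiment 2). U additions fell from 2.80 ± 0.103 to 2.25 ± 0.186% (-0.0445 points per hour, adjusted permutation p = 2.2e-05). The canonical sequence fell from 51.3 ± 3.46 to 46.5 ± 1.14% (-0.374 points per hour, adjusted permutation p = 2.2e-05) and 5′ templated extensions fell from 0.374 ± 0.025 to 0.294 ± 0.017% (-0.0065 points per hour, adjusted permutation p = 2.2e-05). In the controls the 3′ non-templated share was 12.0% in unlabelled total, 14.2% in total 4SU and 12.8% in the negative extraction. In the same order C additions made up 1.546, 1.669 and 0.447% and 5′ templated extensions 0.363, 0.345 and 0.26%. The 12 h means of these classes lie within the range of the controls. U additions made up 2.712, 2.835 and 3.089% and the canonical sequence 54.4, 52.3 and 58.2%, each above the 12 h mean. Additions of mixed bases made up 4.487, 5.985 and 4.514%, each below the 12 h mean.

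Of the 11 classes 7 passed; trimmed forms, 5′ non-templated additions and A and G additions did not (adjusted permutation p = 0.613, 0.471, 0.0969 and 0.0869). A and G additions did pass without 0 h (0.0345 and 0.00533) and without experiment 1 (0.0347 and 0.0496). A fixed mix of the 132 miRNAs with enough counts, an alternative chosen after seeing the data, turned the rise of 3′ templated extensions (0.147 points per hour, adjusted permutation p = 0.0236) into a slope of -0.111, brought the 3′ non-templated slope to 0.114 and the canonical slope to -0.136, and put A additions (0.0514) and trimmed forms (0.137) past the threshold. At that mix the slopes were also smaller for additions of mixed bases (0.078), C (0.0116) and U (-0.0271) and for 5′ templated extensions (-0.0033), each still past the threshold. The rise of 3′ templated extensions was also lost without experiment 2 and without 0 h (adjusted permutation p = 0.346 and 0.322). Within single miRNAs, the 3′ non-templated share had a positive slope in all 3 experiments for 48 of the 132 and a negative one for 15, where chance gives 16.5 each way; for A additions the counts were 53 and 11, and for U additions 8 and 33.

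**Figure D4:**
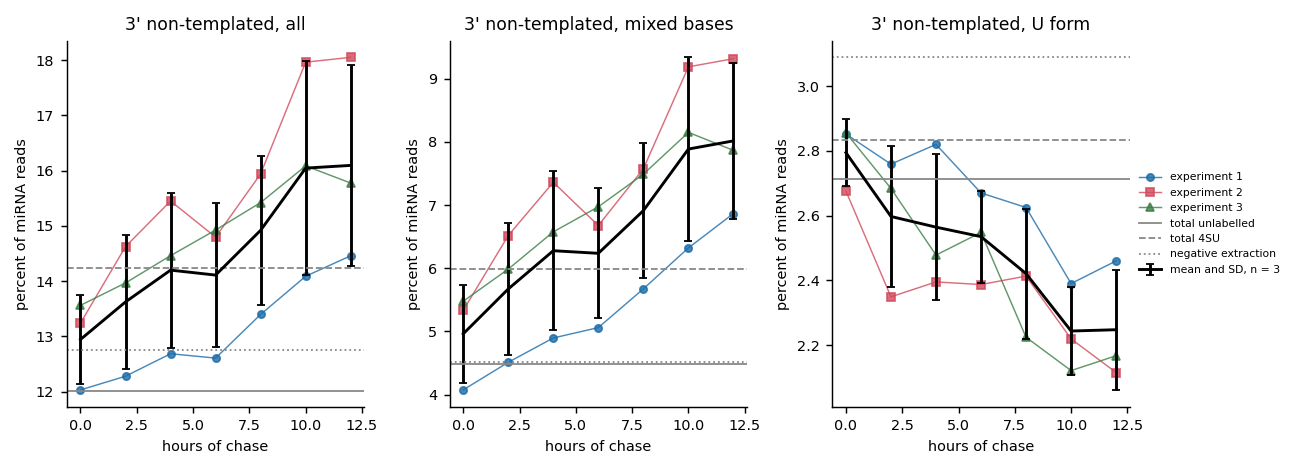
Percent of miRNA counts against hours of chase for all 3′ non-templated additions, additions of mixed bases and U additions, as mean ± SD (n = 3), with lines for the 3 control libraries. Mixed-base additions go from 4.96 to 8.02% and U additions from 2.80 to 2.25%.

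Labelled RNA at 0 h was compared with the total RNA of 4SU-pulsed cells to see which miRNAs were rich or poor among labelled molecules. When the total 4SU library was taken, and from which experiment, is not given in the sources used here, so the ratio need not compare RNA of one moment. Far lower in labelled RNA were miR-301a-3p (log2 ratio -5.76 ± 1.05, SD, n = 3; 64.0 ± 35.6 against 3036 CPM), miR-19b-3p (-4.85 ± 0.50), miR-450b-5p (-4.63 ± 0.30), miR-30e-5p (-4.14 ± 0.59; 565 ± 221 against 9479 CPM) and miR-29b-3p (-4.04 ± 0.37). The highest ratios were those of miR-205-5p (4.32 ± 0.84; 710 ± 403 against 30.9 CPM), miR-676-3p (3.25 ± 0.55), miR-146b-5p (3.05 ± 0.60; 2397 ± 860 against 274 CPM), miR-501-3p (2.73 ± 0.31) and miR-29b-1-5p (2.30 ± 0.80). Against unlabelled total RNA, the total 4SU library was itself low in miR-205-5p, miR-676-3p and miR-146b-5p (log2 ratios -2.52, -2.10 and -2.22) and high in miR-450b-5p, miR-19b-3p, miR-301a-3p and miR-30e-5p (1.97, 0.88, 0.86 and 0.84). The let-7 family stood apart, with all 9 members higher in labelled RNA and a median log2 ratio of 1.58, at percentile 99.9 of random lists of like expression. The miR-30 family (median -1.87, percentile 0.2) and the miR-29 family (median -3.17, percentile 0.7) were lower for each of their 5 and 3 members, and the let-7, miR-30 and miR-29 medians kept their signs with TMM-scaled values (1.78, -1.67 and -3.00). The miR-181 family had a median of 0.91 (percentile 94.7) and the target-directed group -0.94 (percentile 8.6).

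In all, 99 of 414 miRNAs differed more than 2-fold in the same direction in 3 of 3 experiments, 28 higher and 71 lower. TMM scaling, which moved the median of all miRNAs from -0.02 to 0.17 log2, gave 39 higher and 57 lower. There was 1 total 4SU library, so no test was made, and labelled and total libraries never shared a run code. let-7 miRNAs made up 24.6 ± 3.0% of labelled counts at 0 h and 22.4 ± 4.6% at 12 h, against 10.8% in unlabelled total RNA, 8.66% in total 4SU RNA and 32.6% in the negative extraction (Wilson interval 32.4 to 32.7%).

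**Figure D5:**
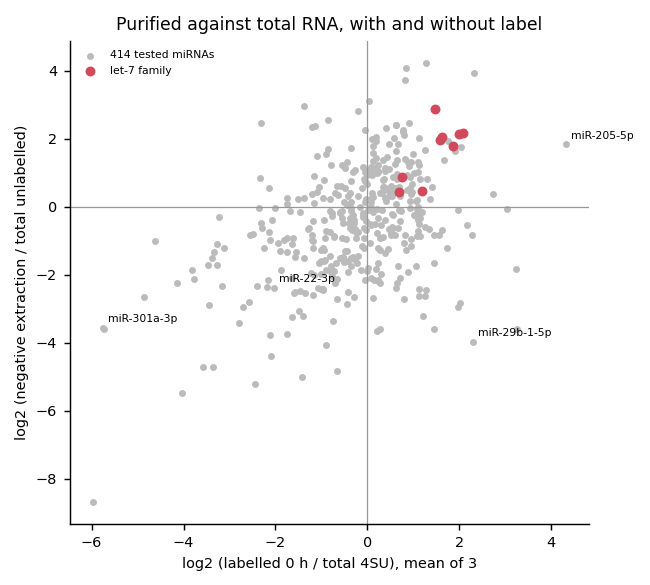
Log2 ratio of labelled RNA at 0 h to total 4SU RNA (x axis, mean of 3 experiments) against log2 ratio of the negative extraction to unlabelled total RNA (y axis), 1 point for each of 414 miRNAs, with the let-7 family in red. The 9 let-7 members lie above 0 on both axes.

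The negative extraction, made from cells that never received 4SU, shows what the purification returns without label. It gave 283922 miRNA counts, of which the most abundant were let-7f-5p (147977 CPM), let-7i-5p (72509 CPM), miR-143-3p (63919 CPM), miR-92a-3p (63880 CPM) and miR-27b-3p (56357 CPM). Across miRNAs, which are not independent replicates, its levels had a Spearman's rho of 0.879 to 0.897 with the 0 h labelled libraries, against 0.869 and 0.866 with unlabelled and 4SU total RNA. The 0 h libraries had 0.88 to 0.907 with total 4SU RNA and 0.939 to 0.976 among themselves. Its 95% counting interval lay outside the range of the 3 0 h libraries for 108 of 414 miRNAs, 53 higher and 55 lower. The split depends on the scaling: with the 10 most abundant miRNAs left out of the totals it was 40 higher and 63 lower. How much RNA entered each library is not given in the sources used here, so the share of unlabelled RNA in the purified libraries cannot be computed.

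Total RNA of 4SU-pulsed cells was set against that of unlabelled cells to see what the pulse itself altered. The most abundant miRNAs differed little: miR-22-3p had 192630 CPM without and 169206 with 4SU, miR-21a-5p 134101 and 110089, miR-143-3p 92715 and 94688, miR-27b-3p 69338 and 68326, and miR-92a-3p 58755 and 74624. The 2 libraries had a Spearman's rho of 0.969 across miRNAs. Of 414 miRNAs 65 differed more than 2-fold, 42 higher and 23 lower after 4SU, with a median log2 ratio of 0.31; with at least 50 counts in both libraries it was 35 of 275, 25 higher and 10 lower. At the extremes, chosen after their values were seen, were miR-10a-5p (log2 ratio 2.96) and miR-340-5p (-2.54). With 1 library each, no test was possible.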

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

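The tests of depth, of labelled against total RNA, of the let-7 family and of the 3′ non-templated share were chosen only after the result was seen, and the thinning of libraries is an alternative added after seeing the data; the other tests here were fixed earlier.

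The relative slope before and after 4 h differed for 18 miRNAs with the experiment as a block, by edgeR's test of the difference between these stretches of the chase. Of 100 assignments of the time points within experiments, the real one included, 3 gave as many, a share under 0.05. Shuffling also removes slopes that are even over the chase. The share therefore cannot decide whether chance gives as many changes of slope where such slopes exist. The highest other gave 42, more than the real 18, and the cause was not tested. Without the block the count was 0 in edgeR (20 at an unadjusted p under 0.05, 5 in DESeq2, 0 in limma-voom). A count of 0 is matched by 100 of 100 assignments by definition, so they cannot tell anything about chance, and the highest other gave 0. Groups of 3 libraries were not tested for single libraries that stand apart.

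The slopes over the chase are the first pattern: of 100 assignments of the time points only the real 1 gave as many as 51 miRNAs without the block (highest other 0), and only the real 1 as many as 132 with it (highest other 2), so chance can be excluded for both. With every library thinned to 1133048 counts, 104 of 132 miRNAs stayed called with the same sign in the fit with the block. That argues against falling depth as the whole cause for the calls of this fit. Without the block 35 of the 51 stayed called, too few under the bound chosen to argue against depth. The calls of miR-7224-3p and miR-450b-5p were among those lost (edgeR adjusted p = 0.106 and 0.121). Unlabelled RNA carried through the purification would leave each miRNA between its 0 h level and the control libraries, and 3 of 63 risers ended above that range in all 3 experiments (0 of 282 uncalled miRNAs, Fisher's exact p = 0.00585) and 7 of 69 fallers below it (10 of 282, Fisher's exact p = 0.0529). The bound set earlier on these p-values was wrong, since called miRNAs were selected for a difference from 0 h and uncalled ones were not, so carried-over RNA and unequal decay cannot be told apart. Unequal decay of miRNAs, which the chase was designed to show, stays open for the whole pattern as a hypothesis.

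At single time points the splits of 6 libraries are too few for a share under 0.05. For 12 h against 0 h, 1 of 10 splits gave as many as the real 5 (highest other 0), and with the block 1 of the 4 splits that part the libraries of every experiment gave as many as the real 90 (highest other 0). For 2 h against 0 h the real count in edgeR was 0 (10 miRNAs at an unadjusted p under 0.05, 1 in DESeq2 and 1 in limma-voom). A count of 0 is matched by 10 of 10 splits by definition (highest other 0), so they cannot tell anything about chance. With the block 1 of 4 gave as many as the real 14 (highest other 0).

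The difference between labelled and total RNA at 0 h is the second pattern, and a candidate explanation is purification and library steps that act without the label, or the run code, which labelled and total libraries never share. Of the 71 miRNAs lower in labelled RNA, 61 were also lower in the negative extraction than in unlabelled total RNA, against 189 of 343 other miRNAs (Fisher's exact p = 5.06e-07), and all 9 let-7 members were higher in the negative extraction, by a median of 1.97 log2 against 1.58 in labelled RNA, both of which such steps would give. Of the 28 miRNAs higher in labelled RNA, 13 were also higher in the negative extraction, against 150 of 386 others (Fisher's exact p = 0.431). For these the candidate cannot be told apart from faster synthesis in the pulse, which was not tested. The planned comparison of the ratio with uridine content was not run, so a part played by uridine content is not settled either. No negative extraction with the run code of experiment 2 or 3, and no total RNA library with that of any experiment, is among the 24 libraries.

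The rise of the 3′ non-templated share is the third pattern, and a changing mix of miRNAs is not its whole cause, since the slope at a fixed mix was 0.114 percentage points per hour (permutation p = 2e-05) against 0.268 with the mix as it was. Unlabelled RNA carried through the purification would keep the 12 h share within the range of 0 h and the controls; it ended above that range by a mean of 1.86 points (SD 1.82, n = 3), by 0.223, 3.82 and 1.54 points in experiments 1, 2 and 3. That mean barely exceeds its spread. For additions of mixed bases alone the excess was 2.03 points (SD 1.23), with 0.881, 3.33 and 1.88 points. The controls are single libraries, and only the negative extraction shares a run code with labelled RNA, that of experiment 1. The 3′ non-templated share already differed between experiments at 0 h (12.0, 13.2 and 13.6%), so shifts between run codes cannot be separated from the excess. Carried-over RNA as the whole cause is therefore neither excluded nor shown. A changing mix may still account for part of the rise, and carried-over RNA for part or all of it. Additions that build up on ageing miRNAs stay open as the biological hypothesis.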

How the results depend on the processing

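Thinning to equal depth, combinations of the block with another choice, the fixed mix of miRNAs, the arm limit of 100 CPM, arms without 0 h, isoforms without an experiment or 0 h, and list tests combining the block with an estimated correlation or fry were chosen after seeing the data; the others were planned. Unless a reason is given, the cause was not tested.

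The slope count of 51 was within 1.5 times in 27 planned settings, among them 3 other scalings, 2 filters, DESeq2, limma-voom and 20 of 21 single libraries left out; it was 29 without the 0 h library of experiment 1, 17 without 0 h, 22 without 12 h, and 15 to 77 without an experiment. With the block it was 132, with the block and DESeq2 size factors 139, total counts only 147, thinned libraries 108, or without 0 h 97. For 12 h against 0 h the main count was 5 and became 14 with total counts only, 8 with upper-quartile scaling, 10 with no filter, 15 in DESeq2, 0 to 14 without an experiment, and 0 thinned or with the 6 libraries alone. Leaving out single libraries gave 0 (0 h or 12 h of experiment 1, 0 h of experiment 2, 12 h of experiment 3) or 2 (0 h of experiment 3). With the block it was 90, and 92, 101, 72 and 45 with DESeq2 size factors, total counts only, thinning or the 6 libraries alone.

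For 2 h against 0 h the main count was 0 in edgeR (10 at an unadjusted p under 0.05), and 1 in DESeq2, 1 in limma-voom and 14 with the block. With the block it was 14 with DESeq2 size factors, 14 with total counts only, 13 thinned and 13 with the 6 libraries alone. For the change of slope at 4 h the main count was 0 in edgeR (20 at an unadjusted p under 0.05), 5 in DESeq2, 0 in limma-voom, 0 to 3 without an experiment (3 without experiment 2), 18 with the block, and 17, 17 and 15 with the block and DESeq2 size factors, total counts only or thinning.

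The arm slope kept its sign in 10 of 10 alternatives and its side of the threshold in 9, but its size ran from -0.0185 (without experiment 2) to -0.0501 (pseudocount 0.1 CPM), against -0.0282; with both arms at 10 CPM or more it was -0.0225 (permutation p = 0.0501). The 3′ templated slope reversed to -0.111 at the fixed mix. Lists called by camera, 3 in the main test, were 4 with the block, 0 with an estimated correlation, 0 with the block and an estimated correlation, and 1 to 3 without an experiment (1 without experiment 2). fry, which tests a list against no change and not against other miRNAs, called 2 lists, or 6 with the block. The 65 miRNAs that differed between the total libraries were 35 with at least 50 counts in both, where fewer miRNAs were compared. The block changed no called direction among the 51 slopes. For named miRNAs, settings fixed earlier left 2078 slope values on the same side of the threshold, took 106 below it and brought 52 past it. The 2078 include slopes that were not called in the main test, while the 106 can only come from slopes that were. Reversals were counted only for slopes called in the main test, and there were 0. A change of sign in the other slopes was not counted. For named hairpins, settings fixed earlier left 194 arm differences within their SD over experiments and moved 7 further. Settings chosen later left 29 and moved 1. Depth limits scarce miRNAs most: 3 counts were 2.65 CPM at 12 h of experiment 2 and 10.6 CPM in the negative extraction. The planned comparison with uridine content was not run.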

Other observations

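The examples of single miRNAs and the test of slopes against the total profile were chosen only after the result was seen; the tests of neighbouring genes were fixed earlier.

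Single miRNAs with a mean of at least 1000 CPM differed in how their 3′ ends changed over the chase. In miR-322-5p, a member of the extended miR-16 family, non-templated additions went from 29.8 ± 3.64 to 41.7 ± 2.67% of its counts between 0 and 12 h (SD, n = 3) and U additions from 25.5 ± 2.40 to 36.8 ± 2.86%, while the U share of all miRNA counts fell. In miR-99b-5p A additions went from 8.41 ± 0.49 to 12.5 ± 0.22% and U additions from 4.80 ± 0.20 to 3.03 ± 0.45%. Non-templated additions went from 46.4 ± 5.02 to 53.8 ± 2.79% in miR-92a-3p, from 33.2 ± 4.02 to 38.5 ± 5.60% in let-7b-5p and from 11.7 ± 1.88 to 17.4 ± 2.68% in miR-29a-3p. The opposite direction was seen in miR-23b-3p (43.4 ± 0.76 to 40.7 ± 1.28%) and miR-191-5p (6.16 ± 0.11 to 4.41 ± 1.37%). Each had 1 direction in all 3 experiments, and single miRNAs were not tested.

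miRNAs of other cell types were also present in the negative extraction. The epithelial miR-203-3p stood at 70.4 CPM there (20 counts, 95% interval 43.0 to 109), against 2.03 ± 0.91 CPM in labelled RNA at 0 h and 2.81 and 0.221 CPM in unlabelled and 4SU total RNA. miR-205-5p stood at 648 CPM (interval 558 to 749), against 710 ± 403 CPM in labelled RNA at 0 h, 182 CPM in unlabelled and 30.9 in 4SU total RNA. The blood cell miR-486a-5p stood at 321 CPM, against 359 ± 152, 217 and 232 CPM.

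One hypothesis was that miRNA genes of one cluster, whose arms come from shared transcripts, have alike slopes. Among genes at most 10000 bases apart, the median absolute difference in slope was 0.0421 log2 per hour over 110 pairs in 29 clusters, against 0.0449 for shuffled slopes (permutation p = 0.328). Outside the Sfmbt2 cluster it was 0.0336 over 59 pairs in 27 clusters, against 0.043 (permutation p = 0.092). Each gene entered by its most abundant arm with a unique name, which sets guide against passenger strands in some pairs, such as miR-15a-5p and miR-16-1-3p. Since arms differ, the test cannot decide for or against sharing, whatever bound had been set, and the question stays open.

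Another hypothesis was that miRNAs scarce in labelled RNA at 0 h relative to total RNA, such as miR-301a-3p, are lost more slowly. Across 414 miRNAs, which are not independent replicates, the ratio of total 4SU to 0 h RNA in experiment 1 had a Spearman's rho of 0.379 with the mean slope from 2 h on in experiments 2 and 3. The rho was 0.452 with unlabelled total RNA and 0.188 with the negative extraction in its place. Carried-over unlabelled RNA could give the same sign, so these data cannot separate it from slower loss.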
